A study of Mus musculus with 2 samples.

How the data were processed

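RNA was measured in 2 areas of the granule layer of the mouse cerebellum, cut out by laser capture and made into 1 sequencing library each. Per the labels, the tissue was adult male wild-type of the B6NCrl mouse strain aged 8 months, each area covered 18000 square microns, the starting quantity was 50 cells, the molecule was total RNA, and the general library protocol was Smart-seq, a method that copies and amplifies full-length polyadenylated transcripts from few cells. The labels name the assay single cell RNA sequencing, although each library holds an area of many cells. Both areas carry the same donor label, which for an inbred strain may stand for the strain, and are numbered as biological replicates 1 and 2. They were treated as 2 areas under 1 donor label, in 1 group. No contrast between groups exists in this design, and the spread given here covers capture, amplification and sequencing of areas, and whether it also covers animals is not known. With 2 areas no permutation test can pass 0.05, so no p-value between conditions is given.

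The deposited tables hold 1 row per gene or per transcript. Per the file headers, the deposited expected counts are estimates that share reads among genes and isoforms and need not be whole, and per the deposited notes the genome build was mm10 and the annotation GENCODE M4. The deposited TPM values (transcripts per 1e6) and the deposited FPKM values (fragments per kilobase per 1e6 fragments) were normalized by the authors for transcript length and library total, per the file headers. The deposited score columns hold bounds of an interval on TPM, whose level the headers do not state, and a posterior standard deviation of the count, which measures how far reads could move between similar genes. The deposited percent column of the transcript tables gives each transcript's share of its gene. The aligner, the counting program and its version, read filters and the use of strand are not given in the sources used here. Smart-seq amplifies before sequencing and the files give no molecule counts, so reads are not independent molecules, and every interval or floor here covers counting error only.

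Each gene table has 69691 rows. Of these, 43346 have Ensembl gene IDs, 97 are spike-in or control sequences, and 26248 carry numeric IDs with a median length of 73 bases. The numeric rows held 10 counts in replicate 1 and 6 in replicate 2 and were left out with the spike-ins from gene totals and tests. Gene names, types and coordinates were taken from GENCODE M21 on GRCm38, the same build as mm10, by matching IDs without their version: 42462 of the 43346 IDs matched. The unmatched IDs held 0.432% and 0.435% of gene counts and stayed in the totals without a name. Because M21 is later than M4, a gene type or transcript name can differ from the one used for counting. Total expected counts were 20532709 in replicate 1 and 19939370 in replicate 2. A count of 0 allows up to 3 counts, or 0.150 and 0.156 counts per 1e6 gene counts in the 2 libraries.

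A gene was called detected in a library at a TPM of at least 1 and an expected count of at least 5. Agreement was measured across genes with a summed expected count of at least 10, by Pearson and Spearman correlation of log2(TPM + 1), by the number of genes over 4-fold apart on that scale, and by the biological coefficient of variation, the square root of edgeR's common dispersion with TMM scaling and an intercept only, on expected counts rounded to whole numbers. Counting error was tested per gene with a two-sided exact binomial test on rounded counts against the share of the library totals, with Benjamini-Hochberg adjustment at 0.05. That test compares these 2 libraries, not conditions, and takes reads as independent.

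Before the data were examined, 19 lists of cell type and sex-linked markers, 18 lists of functional gene families and 30 genes for isoforms were fixed. A list's median TPM was placed among the medians of 10000 random lists of the same size drawn from the protein-coding genes. The granule neuron list was compared with every other cell type list by the difference of mean log2(TPM + 1), leaving out members held by both. For the difference between the areas, the median log2 ratio of TPM + 1 of each list's expressed members was placed among 10000 random lists matched on mean expression in 20 bins, and a list beyond the 2.5 or 97.5 percentile was called outside. Members were taken as expressed from the mean of both libraries, a reading of the planned wording that was settled after values had been seen, so a version with members detected in both libraries was added after seeing the data, and its values are given where it changes whether a list lies outside. Lists with fewer than 3 expressed members got no ratio. Scn2a1, Atp5f1a and Atp5f1b matched no gene name and are other names of genes already listed. Genes were named from the 4 highest and the first 3 members of each list, the 20 highest nuclear protein-coding genes, and the 8 nuclear protein-coding genes in each direction furthest apart between the libraries at a mean TPM of at least 20 and at least 50 counts in the higher library, and from the isoform genes that passed their filter; not every gene the rule allows is printed. A gene named outside the rule is said to have been chosen after its values were seen.

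For isoforms, genes with at least 2 listed transcripts, a TPM of at least 10 and an expected count of at least 50 in each library were kept. The transcript with the largest share was compared between libraries, and a gene was called dominated at a share of at least 50% by the same transcript in both.

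The alternatives were other thresholds, pseudocounts of 0.1 and 5, no filter or stricter filters, DESeq2 size factors, library totals or spike-in totals, FPKM or posterior mean TPM in place of TPM, other backgrounds for the random lists, mitochondrial genes left out, and each library left out in turn. A lowess trend on transcript length and then on GC content was removed from the log2 ratios as an alternative added after seeing the data. The methods were tested on simulated data. For the agreement of the areas, simulated coefficients of variation of 0.1 and 0.3 came back as 0.100 and 0.296 over 16361 and 16291 genes. For the counting test, 100% of 100 genes changed 4-fold and 78% of 100 changed 1.5-fold were recovered with Poisson noise, and 6 of 16470 unchanged genes were called. For the difference by list, also with Poisson noise, a list raised 1.5-fold lay at percentile 100 and 1 of 30 unchanged lists fell outside. The real libraries differ by more than Poisson noise, so the counting and list simulations do not show performance at the real noise. The work used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and statsmodels 0.14.6, with edgeR 4.0.16 and DESeq2 1.42.0 in R 4.3.3.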

Results

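The granule layer of the cerebellum is packed with granule neurons, small excitatory cells that take input from mossy fibres and send parallel fibres to Purkinje cells. The labels describe 2 captured areas of this layer from adult male tissue aged 8 months, with 18000 square microns and a starting quantity of 50 cells for each. They form 1 group, the granule layer, with n = 2 areas under the same donor label. The labels also number the areas as biological replicates 1 and 2, and whether they came from 1 animal or from 2 is not stated. Replicate 1 held 20532709 expected counts and replicate 2 held 19939370, of which 19962271 and 19261911 belonged to annotated genes. Values below are the mean of both areas ± SD (n = 2) unless a replicate is named. Cbln3, Slc17a7, Slc17a6, Stx1a, Camk4, Camk2a, Gabre, Gabrq, Scn3a, Cd68, Mal, Tagln, Kcnj8 and mt-Co3 are list members named after their values were seen. The SD is the spread between areas, and whether it holds any spread between animals is not known.

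The first question was how many genes the captured areas showed and whether the areas gave the same levels. In both libraries 12523 genes were detected, with 13337 in replicate 1 and 13236 in replicate 2. The shared genes included 10817 protein-coding genes, 793 long noncoding genes and 497 pseudogenes. Across 16636 genes, which are not independent replicates, log2(TPM + 1) had a Pearson correlation of 0.982 and a Spearman correlation of 0.970. There were 36 genes over 4-fold apart, 19 of them higher in replicate 1 and 17 in replicate 2; the number was 719 with a pseudocount of 0.1, 153 with no filter and 8 with a pseudocount of 5. The 5 with a mean TPM of at least 20 were the globin genes Hba-a2, Hbb-bs, Hba-a1 and Hbb-bt, which encode the chains of haemoglobin, and Sln, which encodes the calcium pump regulator sarcolipin; all 5 were higher in replicate 1. The biological coefficient of variation between the areas was 0.272. The libraries differed by more than counting error. The chi-square of their counts was 17.3 times its degrees of freedom, and 7923 genes (47.6%) lay beyond counting error by the exact binomial test with Benjamini-Hochberg adjustment. Of these, 3986 were higher in replicate 1 and 3937 in replicate 2. With counts divided by 10, as if 10 reads came from 1 molecule, 117 genes lay beyond it.

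Granule neuron markers stood out among the cell type lists. Their median was 104 TPM, above all 10000 random lists of the same size (percentile 100), and 24 of the 25 members were detected in both areas. Gabra6, the GABA-A receptor subunit typical of granule cells, was the highest at 1006 ± 114 TPM, with 36105 and 40856 counts (ENSMUSG00000020428.9, chromosome 11, 42306437 to 42321072). The Rac regulator Chn2 was at 618 ± 26.5 TPM. Neurod1, a transcription factor of neuronal differentiation, was at 427 ± 15.5 TPM. Etv1, an ETS transcription factor of maturing granule cells, was at 363 ± 19.7 TPM. Neurod2 was at 23.1 ± 2.22 TPM and the giant cadherin Fat2 at 16.8 ± 2.80 TPM. The synaptic organizers Cbln3 and Cbln1 were at 205 ± 8.01 and 177 ± 0.339 TPM. The vesicular glutamate transporter of granule cells, Slc17a7, was lower at 12.1 ± 0.240 TPM, with 581 counts in each library.

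Apart from red blood cells, markers of other cells in or near the layer were present at lower levels. The list of Bergmann glia and astrocytes had a median of 21.1 TPM (percentile 99.8), led by Aldoc at 265 ± 15.4, Sparcl1 at 127 ± 13.4, S100b at 119 ± 0.262 and the gap junction gene Gja1 at 96.7 ± 6.63. Aqp4, the water channel of astrocytes, was at 69.7 ± 3.23 TPM and Gfap at 6.18 ± 0.544. Oligodendrocyte markers had a median of 16.0 TPM (percentile 99.0), with the myelin gene Mbp at 280 ± 44.4, Apod at 151 ± 83.5 and Trf at 90.0 ± 2.74. Mobp was at 87.7 ± 9.82 TPM. Against random lists drawn only from genes detected in both areas, the glial lists fell to percentiles 88.3 and 70.4, while the granule list stayed above the random range. Red blood cell markers had a median of 237 TPM (percentile 100), above that of the granule list. It was 467 TPM in replicate 1 and 19.6 in replicate 2, so the value rests on replicate 1.

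None of the remaining non-neuronal lists lay above the range of the random lists of protein-coding genes. Against random lists of all annotated genes, endothelial and microglia markers did, at percentiles 99.35 and 99.04. Endothelial markers had a median of 5.11 TPM, with Bsg at 478 ± 51.0, a gene that many cell types also express, Ly6c1 at 130 ± 14.7, Ly6a at 81.2 ± 8.22 and the tight junction gene Cldn5 at 4.10 ± 1.41. Microglia markers had a median of 4.13 TPM, with Ctss at 24.3 ± 4.78 and the complement gene C1qb at 21.9 ± 3.54. Mural cell markers had a median of 2.66 TPM, from 1.065 in replicate 1 and 5.315 in replicate 2. Among them, the pericyte gene Rgs5 was at 23.9 ± 5.66, Higd1b at 8.85 ± 3.83 and Myl9 at 8.79 ± 8.03. Meningeal fibroblasts had a median of 0.255 TPM, although Ptgds, which oligodendrocytes also make, reached 339 ± 122. Oligodendrocyte precursors had a median of 0.55 TPM, with Bcas1 at 11.9 ± 2.12, Olig1 at 4.36 ± 0.912 and Cspg4 at 0.185 ± 0.0495. Choroid plexus markers had a median of 0, and the transthyretin gene Ttr had 0 counts in both libraries.

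Other neurons were also low. Purkinje cell markers had a median of 3.77 TPM, at percentile 74.7 among protein-coding lists but 99.3 against random lists of all annotated genes. Of them, Gng13 stood at 163 ± 31.6, Pcp2 at 125 ± 47.4 and Pcp4 at 90.8 ± 31.1, while Calb1 was at 7.36 ± 0.75 and Car8 at 1.95 ± 0.375. Markers of Golgi cells and other inhibitory neurons had a median of 3.14 TPM, from 4.465 in replicate 1 and 1.885 in replicate 2. The GABA-synthesizing enzyme Gad1 was at 19.6 ± 1.81 and the glycine transporter Slc6a5 at 2.41 ± 0.283. Unipolar brush cell markers had a median of 5.12 TPM, with Calb2 at 62.9 ± 18.7, Eomes at 5.04 ± 1.48 and Lmx1a at 0.290 ± 0.410; Plcb4, at 166 ± 1.97, is also a gene of other cerebellar neurons. Molecular layer interneurons had a median of 0.530 TPM, with Pvalb at 32.4 ± 0.976 and Kit at 0.810 ± 0.0424. Forebrain neurons had a median of 0.0250 TPM, but 2 of the 11 members, Prox1 at 13.4 ± 0.863 and Ppp1r1b at 11.9 ± 0.0849, were detected. The progenitor list had a median of 0.115 TPM, with Cdk1 at 2.38 ± 1.48, Mki67 at 0.0300 ± 0.0141 and Atoh1 at 0 counts. The list of liver and muscle genes had a median of 0 (percentile 2.13). No list can lie lower and some random lists also had a median of 0, so it lay at the floor of the random range. Its member Alb was at 0, although Acta1 at 7.03 ± 0.898, Apoa1 at 5.80 ± 1.23 and Mylpf at 5.38 ± 1.93 were detected. The 4 Y-linked genes were at a median of 43.4 TPM, led by Eif2s3y at 163 ± 25.4, and Xist was at 0.0200 ± 0.0141; the labels give male. Uty, Ddx3y and Kdm5d were at 43.4 ± 2.28, 43.4 ± 1.85 and 37.7 ± 8.29 TPM.

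Set directly against each other, the granule list was above 17 of the 18 other lists in both libraries. The difference of mean log2(TPM + 1) was 1.37 ± 0.23 against oligodendrocytes, 1.67 ± 0.11 against Bergmann glia and astrocytes, 2.33 ± 0.22 against endothelial cells and 3.22 ± 0.07 against Purkinje cells, folds of 2.59, 3.18, 5.04 and 9.29. These folds depend on how a list is summarized: from list medians the same differences were 2.60, 2.25, 4.12 and 4.41, which puts oligodendrocytes after Bergmann glia and astrocytes in closeness to the granule list. It was 3.34 ± 0.06 against microglia, 3.29 ± 0.33 against unipolar brush cells, 3.99 ± 0.35 against Golgi cells and 4.07 ± 0.60 against mural cells. Against the 4 Y-linked genes it was 0.15 ± 0.05, but 1.23 from list medians and 3.81 from summed TPM. The exception was the red blood cell list, at -0.75 in replicate 1 and 1.81 in replicate 2. Marker genes differ in how abundant they are within their own cell type, so a fold between lists is not a ratio of cells.

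**Figure D1:**
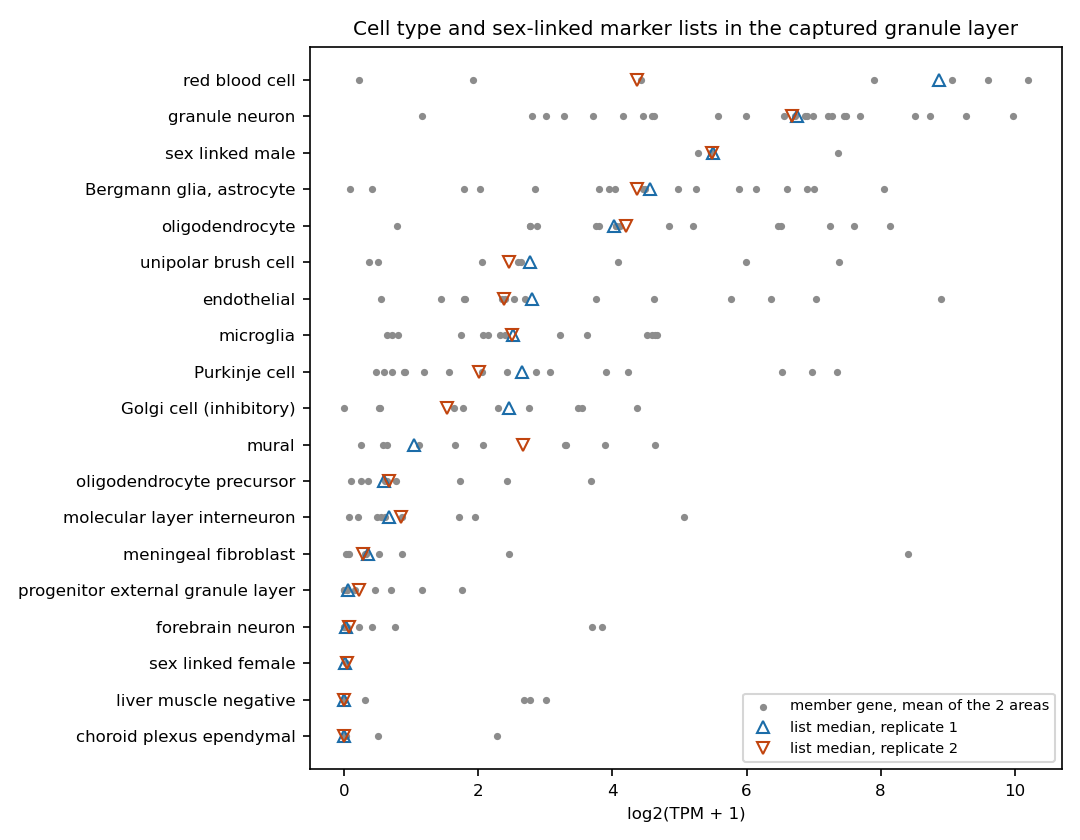
Levels of the cell type and sex-linked marker lists, with log2(TPM + 1) on the x axis and 1 list per row. Grey points are single genes as the mean of both areas and triangles are the list medians of each replicate. Granule neuron medians lie at 107 and 101 TPM, and the red blood cell medians lie furthest apart, at 467 and 19.6 TPM.

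Families of synaptic and signalling genes were described next, to show what the captured areas express. Their levels belong to the whole area and were not assigned to a cell type. In 13 of the 18 function lists the median lay above the range of random lists. Against random lists of genes detected in both areas, a background added after seeing the data, 9 did, and potassium channels, cerebellar transcription factors, stress genes and clock genes fell to percentiles 43.2, 48.9, 72.6 and 86.2. Synaptic vesicle genes had a median of 57.9 TPM, and 24 of 26 were detected. The SNARE protein gene Snap25 led at 4264 ± 368 TPM, followed by the calcium sensor Syt1 at 193 ± 12.6 and the ATPase Nsf at 151 ± 10.1; Syt2 was at 133 ± 2.79. Stx1a had 0 counts in both libraries, and the glutamate transporter Slc17a6 was at 0.0600 ± 0.0707. Calcium signalling genes had a median of 90.8 TPM, with the calmodulin gene Calm2 at 6225 ± 337, Calm3 at 203 ± 13.6, the calcineurin subunit Ppp3ca at 545 ± 11.7 and Vsnl1 at 432 ± 80.6. Camk4 was at 166 ± 0.0141 TPM and Camk2a at 0.10 ± 0.0566.

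Receptor lists were uneven, with a few subunits high and many near 0. The GABA-A list had a median of 8.53 TPM (percentile 92.9). Besides Gabra6, the extrasynaptic subunit Gabrd was at 119 ± 1.43 and Gabrb2 at 80.3 ± 0.523. Gabra2 was at 13.3 ± 2.26 TPM, Gabra3 at 1.61 ± 0.933, and Gabre and Gabrq had 0 counts. Ionotropic glutamate receptors had a median of 3.02 TPM (percentile 69.7). Gria2 was at 151 ± 15.2, Gria4 at 98.8 ± 3.73, the kainate subunit Grik2 at 74.0 ± 0.863 and the NMDA subunit Grin1 at 47.3 ± 0.870, while Gria1 was at 0.0650 ± 0.0778 and Gria3 at 3.02 ± 0.297. Metabotropic receptors had a median of 2.07 TPM (percentile 51.4), led by Grm4 at 34.9 ± 3.20, with Grm3 at 3.61 ± 1.13 and Grm2 at 2.10 ± 0.898.

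Potassium channel genes had a median of 11.6 TPM (percentile 99.3), led by the A-type channel Kcnd2 at 174 ± 4.07 and the leak channel Kcnk1 at 143 ± 6.62, with Dpp6 at 128 ± 5.29 and Kcnip4 at 123 ± 1.70, which encode partners of Kcnd channels. Kcna1 was at 47.4 ± 2.22 TPM, Kcna2 at 1.14 ± 0.255 and Kcna4 at 0. Sodium channel genes had a median of 43.2 TPM, with Scn2a at 184 ± 27.7, Scn2b at 163 ± 2.39, Scn1a at 107 ± 3.64 and Fgf14 at 98.6 ± 0.665, while Scn3a was at 0.0600 ± 0.0566. Calcium channel genes had a median of 4.50 TPM (percentile 79.2), with the subunit Cacnb4 at 189 ± 3.26, the P/Q-type gene Cacna1a at 70.2 ± 6.02, Cacna1e at 17.9 ± 2.04 and Cacna2d1 at 17.6 ± 2.88.

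Energy and protein synthesis genes were described as further families. Genes of nuclear-encoded oxidative phosphorylation had a median of 1187 TPM and summed to 42383 ± 61.2 TPM, with Cox8a at 4511 ± 17.1, Ndufa4 at 3727 ± 56.6, Cox6c at 2809 ± 108 and Cox6b1 at 2160 ± 50.4. Glycolysis genes had a median of 163 TPM, with Aldoa at 771 ± 36.5, Gapdh at 696 ± 33.9, Tpi1 at 468 ± 13.1 and Ldhb at 447 ± 1.15. Ribosomal protein genes had a median of 358 TPM, and all 54 were detected, led by Rpl41 at 1371 ± 5.44, Rpl38 at 911 ± 8.32, Rps14 at 897 ± 24.6 and Rps29 at 870 ± 13.7; these genes have many pseudogene copies with which reads can be shared. Stress genes had a median of 15.9 TPM, and of the chaperones Hsp90aa1 was at 1230 ± 14.5 and Hspa8 at 938 ± 66.1, Hsp90ab1 at 493 ± 8.24 and Hspe1 at 213 ± 14.2, whereas the inducible Hspa1a was at 1.31 ± 0.0778. Immediate early genes had a median of 1.20 TPM (percentile 45.5), with Egr1 at 19.9 ± 0.0707, Btg2 at 15.6 ± 1.51, Jun at 6.79 ± 0.262, Dusp1 at 6.68 ± 0.431 and Fos at 1.83 ± 0.849.

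Transcription factors of the cerebellum had a median of 12.1 TPM (percentile 99.5). After Neurod1 and Etv1, Nfix was at 164 ± 10.6 and Zic1 at 148 ± 2.95 TPM, while Zic2 was at 23.5 ± 2.43. Circadian clock genes had a median of 20.1 TPM (percentile 99.7), and 17 of 18 were detected. Per3 was at 77.5 ± 2.55, Nr1d2 at 67.4 ± 5.03, Bhlhe41 at 63.5 ± 4.69 and Tef at 62.6 ± 0.283, whereas Arntl was at 8.29 ± 0.445. Nuclear noncoding RNAs had a median of 92.6 TPM, with Malat1 at 86136 ± 3653, Snhg11 at 826 ± 108, Snhg14 at 420 ± 46.9 and Meg3 at 236 ± 25.1. The Malat1 level rests on an estimated length of 592 bases in replicate 1 and 593 in replicate 2. Its locus runs from 5795690 to 5802672 on chromosome 19, so its TPM depends on that short length.

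The 20 most abundant nuclear protein-coding genes included Calm2, Snap25 and the 4 respiratory genes named above. Ppia, a peptidyl-prolyl isomerase, was at 4327 ± 261 TPM, the ubiquitin gene Ubb at 2571 ± 199.7, Usmg5 of the ATP synthase at 2370 ± 22.5 and Actb at 2068 ± 273. Cdr1 was at 1917 ± 13.8, the metallothionein Mt1 at 1903 ± 110, the ferritin chain Fth1 at 1898 ± 352 and the acyl-CoA binding gene Dbi at 1581 ± 17.0. The respiratory genes Cox4i1, Atp5h, Atp5j, Cox6a1 and Cox5b completed the set, at 2067 ± 123, 2030 ± 68.6, 1897 ± 3.22, 1886 ± 53.0 and 1526 ± 3.48 TPM.

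The next comparison asked whether the areas differed in their cell make-up. Of 31 lists with a ratio, 9 lay outside the central 95% of matched random lists, against 1.55 expected by chance. Ratios are log2 of replicate 2 over replicate 1, and the replicates have no order. Oligodendrocyte markers were higher in replicate 2, with a median of 0.25 and 14 of 15 expressed members on that side, among them Apod at 91.5 and 210 TPM and Mal at 29.1 and 42.6. Mural markers were higher in replicate 2 with a median of 1.49, 5 of 7 members. The smooth muscle genes Acta2 and Tagln had 0 counts in replicate 1 against 178 and 106 in replicate 2. Against a floor of 3 counts in replicate 1, they were 61.5-fold and 36.6-fold higher in replicate 2. That floor covers counting error only, and as reads are not independent molecules these folds are not lower bounds. Vtn was at 6.80 and 20.9 TPM. Rgs5 and Kcnj8 lay on the other side, at 27.9 and 19.9 TPM and at 1.70 and 0.630.

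Markers of Golgi cells, microglia and endothelial cells were higher in replicate 1. All 7 expressed Golgi cell markers were, with a median of -0.60; Gad2 was at 7.47 and 4.07 TPM and Lgi2 at 13.1 and 8.24. Microglia markers had a median of -0.32, 8 of 11 members, with Tyrobp at 27.4 and 19.0 TPM against Cd68 at 1.39 and 5.47. Endothelial markers had a median of -0.23, 12 of 13 members, with Itm2a at 63.9 and 42.9 TPM. The red blood cell list was furthest apart at -3.46, 6 of 6 members. Smaller shifts were seen for cerebellar transcription factors at -0.13, mitochondrial mRNAs at -0.09 and nuclear noncoding RNAs at -0.15. The transcription factors lay inside the random range under 4 other settings. Granule markers lay inside the range at 0.04, as did the synaptic vesicle genes at 0.04, ribosomal proteins at 0.01, nuclear oxidative phosphorylation at 0.00 and the clock genes at -0.01. So did Bergmann glia and astrocytes at -0.12, oligodendrocyte precursors at 0.34, molecular layer interneurons at -0.08, unipolar brush cells at -0.05, liver and muscle genes at 0.37 and the Y-linked genes at 0.01. Receptors and channels were inside it too: GABA-A at 0.15, ionotropic glutamate at -0.15, metabotropic glutamate at -0.33, potassium at 0.03, sodium at 0.10 and calcium channels at -0.02. Calcium signalling lay at 0.02, glycolysis at 0.00, immediate early genes at 0.05 and stress genes at -0.02. Purkinje markers were inside it at -0.21 (percentile 2.87). Under other settings, values are given relative to the median of all genes. Mural markers were then at 0.90 with a pseudocount of 5 and 0.58 over all members, and Golgi cell markers at -0.25 with a pseudocount of 5, all still outside. Purkinje markers lay outside under 4 settings, at -0.20 over members detected in both libraries, but at 0.04 over all members the direction turned. Metabotropic receptors lay outside under 3, at -0.61 with TMM scaling and -0.50 over members detected in both libraries, against -0.15 over all members. Unipolar brush cells lay outside only over all members, at -0.30, and were at 0.03 over members detected in both libraries. Bergmann glia and astrocytes lay outside only with a pseudocount of 5, at -0.10.

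**Figure D2:**
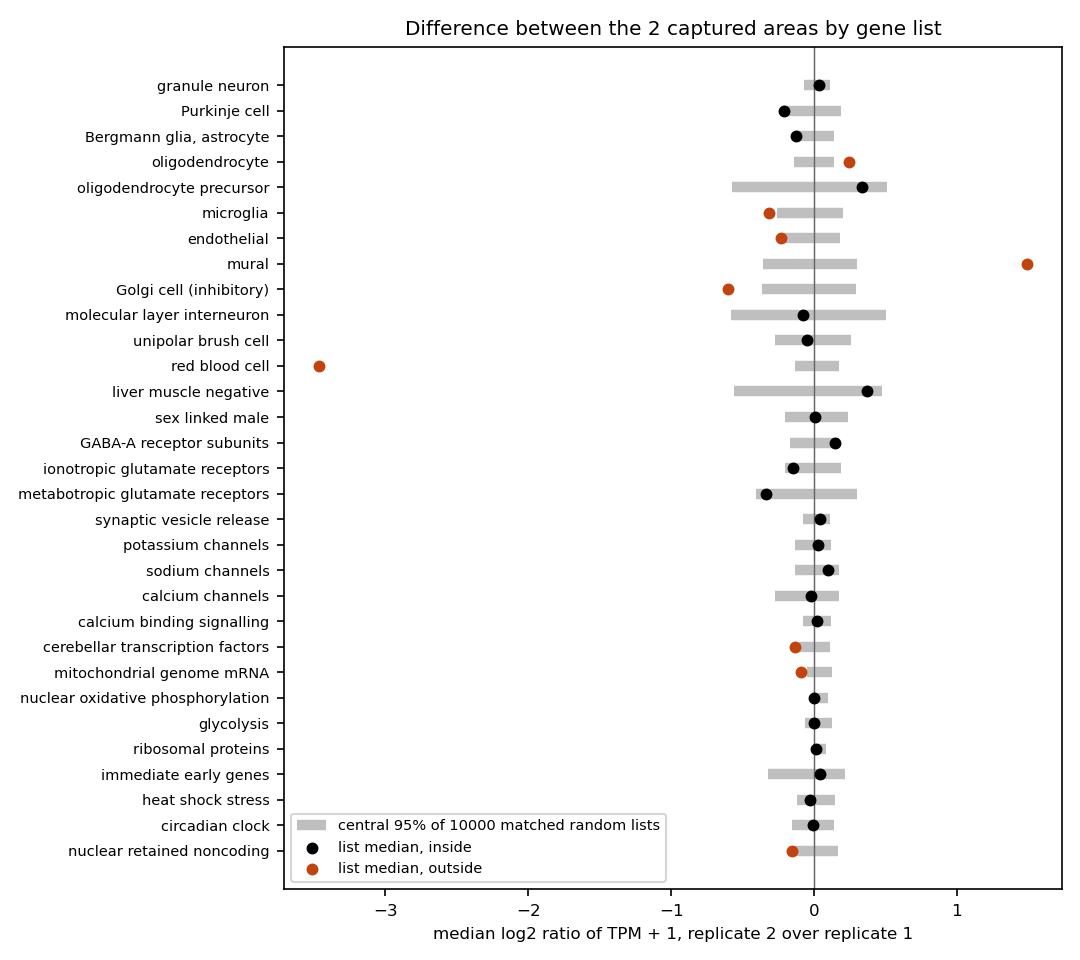
Median log2 ratio of TPM + 1, replicate 2 over replicate 1, of the expressed members of each list. Grey bars are the central 95% of 10000 random lists matched on mean expression, and orange points are the 9 lists outside it. The red blood cell list at -3.46 and the mural list at 1.49 lie furthest from 0.

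Single genes that set the areas apart were few. Among 4447 nuclear protein-coding genes at a mean TPM of at least 20, 10 were over 2-fold apart. Hbb-bt was at 467 TPM in replicate 1 and 6.41 in replicate 2, a fold of 72.9, Hba-a2 at 2178 and 163, Hba-a1 at 982 and 81.3, and Hbb-bs at 1408 and 137. These genes have near-identical copies beside them, on chromosome 11 from 32283511 to 32297298 and on chromosome 7 from 103812524 to 103828096, so reads can be shared between copies. The posterior SD was 20.1% of the count for Hbb-bt in replicate 2 and at most 4.70% for the other globin counts. The split is thus least certain for Hbb-bt in replicate 2. Summed over the 4 genes, 41674 and 3076 counts gave a fold of 13.1 per gene count. Sln had 384 and 4 counts. Lrp1b, an endocytic receptor gene, was 2.68-fold and the vesicle gene Rab3b 2.37-fold higher in replicate 1. Zfp969 was 2.14-fold higher there on 72.7 and 34.2 counts, with a posterior SD of 21.9% and 40.8% of the count from shared reads. In replicate 2, Apod was 2.29-fold and Crip1 2.16-fold higher. Etfrf1, Ube4a, Pcp2, Emc8, Timm17b and Rnaseh2a followed at 1.99-fold to 1.71-fold. For Emc8 the log2 ratio of 0.77 in TPM was 0.24 in TMM-scaled counts, and its estimated length was 1443 bases in replicate 1 and 1016 in replicate 2. No replicate check exists for a difference between single areas.

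Transcripts of the mitochondrial genome took 6.4% and 5.22% of gene counts. The 13 mRNAs had a median of 3856 TPM, with mt-Atp8 at 12877 ± 29.4 TPM, mt-Atp6 at 9907 ± 85.1, mt-Co1 at 6727 ± 681, mt-Cytb at 6329 ± 221, mt-Nd1 at 5936 ± 161, mt-Nd2 at 2738 ± 116 and mt-Nd3 at 1422 ± 178. The ribosomal RNAs had a median of 9534 TPM. Of them, mt-Rnr2 and mt-Rnr1 were at 15470 and 8185 TPM in replicate 1 and at 9391 and 5092 in replicate 2, log2 ratios of -0.72 and -0.68. A block of pseudogenes on chromosome 1 from 24612775 to 24616197 is annotated in the nuclear genome with sequence like that of mitochondrial genes, and its member Gm28437, named after its value was seen, stood at 18405 and 16887 TPM. Counts of mt-Co3, at 3932 and 3780 TPM, had a posterior SD of 135% and 125% of the count, those of mt-Atp6 29.5% and 23.3%, and those of Gm28437 29.0% and 28.0%. These levels are uncertain beyond the SD between areas, as is the median of the mRNAs, which is the level of mt-Co3.

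**Figure D3:**
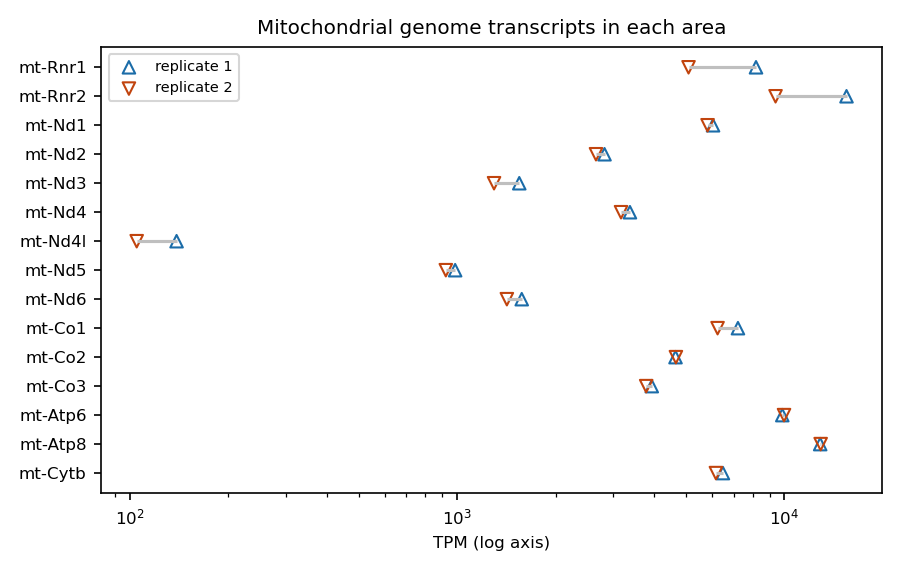
Levels of the 15 transcripts of the mitochondrial genome named in the lists, with TPM on a log axis and 1 triangle per replicate. The 2 ribosomal RNAs, mt-Rnr1 and mt-Rnr2, lie further apart between replicates than the abundant mRNAs.

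Spike-in RNAs, added at known amounts and free of biological difference, gave a technical reference. They took 2.78% of counts in replicate 1 (95% exact binomial interval 2.77 to 2.79) and 3.40% in replicate 2 (3.39 to 3.41). There were 35.0 gene counts per spike-in count in replicate 1 and 28.4 in replicate 2, a ratio of 0.812. Of 96 listed spike-ins, 67 were seen in both libraries, and across them log2 TPM had a Pearson correlation of 0.976. Their coefficient of variation, added after seeing the data, was 0.207 over 69 sequences, scaled by spike-in totals without TMM. With 10 to 100 summed counts, the SD of the log2 ratio was 2.01 for 23 spike-ins and 2.07 for 4662 genes. It was 0.34 and 0.66 with 100 to 1000 (23 spike-ins, 5894 genes) and 0.23 and 0.24 with 1000 to 10000 (10 and 5422). With 10000 to 100000 it was 0.11 and 0.24 (9 and 637). The spike-in values thus rest on few sequences.

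Isoform shares were compared for 4942 genes with at least 2 listed transcripts. In 4440 of them (89.8%) the same transcript led in both libraries, and in 3341 (67.6%) it held at least 50% in both. Of the 30 genes fixed beforehand 25 passed the filter, and 23 had the same leading transcript. Zic1, Cbln1, Fgf14 and Snap25 were made up almost wholly of 1 transcript, at 99.98 ± 0, 100 ± 0, 99.7 ± 0.120 and 98.7 ± 0.226 percent. The pyruvate kinase gene Pkm was led by Pkm-202 at 95.4 ± 1.21 percent. Mbp-211 held 72.6 ± 1.29 percent, Rbfox3-203 66.2 ± 1.53 and Camk2b-209 53.9 ± 1.43. In Gria2, Cacna1a and Ank3 the leading transcript was annotated as a retained intron, at 47.3 ± 1.52, 36.8 ± 0.672 and 37.7 ± 0.361 percent. Shares depend on how the counting program divides reads between overlapping transcripts.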

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

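The tests in this part were chosen after their results were seen, except those that remove a trend with transcript length and GC content, which were written down before.

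Data outside the comparisons held little. Rows with numeric IDs and a median length of 73 bases, whose length is that of transfer RNAs, held 10 counts in replicate 1 and 6 in replicate 2, above the 3 counts that a count of 0 allows. Genes whose IDs were not matched to the reference annotation held 86242 counts in replicate 1 and 83810 in replicate 2, and they went into totals but into no list.

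Globin transcripts were 13.1-fold higher in replicate 1 when the 4 genes were summed, with a counting interval of 12.6 to 13.6, which argues against reads moved between globin paralogs. Less blood in the area of replicate 2 stays open: the other 3 red blood cell genes summed to 872 and 567 counts, a fold of 1.49, but 736 and 538 of these were Bpgm, which is not restricted to blood, so that sum decides nothing. A first rule, itself set after this value was seen, had excluded less blood at a fold under 1.5, and the condition that no single gene may give most of the counts was added afterwards. The 2 remaining genes do not decide it either. Alas2, the enzyme of haem synthesis in red cells, had a fold of 6.70 (interval 3.97 to 11.4). Slc4a1, the anion exchanger of red cells, had 14 and 11 counts and a fold of 1.23 (0.518 to 2.99). These intervals cover counting error only. Genes with 10 to 100 summed counts, as Slc4a1 has, had an SD of the log2 ratio of 2.07 between the libraries. For genes with 100 to 1000 that SD was 0.66, and Alas2, with 122 and 17.6 counts, lies near the lower end of that class.

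The marker lists of oligodendrocytes and mural cells were higher in replicate 2, and those of microglia, endothelial cells and Golgi cells in replicate 1. A lower share of granule cells in 1 area, with the other cells unchanged relative to each other, would raise all 5 lists together. Of the 5 lists, 3 lay on the side of replicate 1 and 2 on the other. A changed share of granule cells beside changes among the other cells is not decided by these sides. Noise of amplification that is independent between genes would leave at most 4 of the 31 lists outside in 95% of cases, and 9 were, with these 5 alone above that number. After a trend with transcript length or GC content was removed, 5 of the 5 lists stayed outside on the same side. Noise shared by the genes of a list, and a difference in the cells caught, stay open and were not tested.

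Mitochondrial ribosomal RNA was lower in replicate 2, at a mean log2 ratio of -0.70, and mitochondrial mRNA was lower by less. The mRNA list lay outside the random range at a median of -0.09, with 10 of 13 members lower in replicate 2. Fewer mitochondria in that area would lower both alike, but the median log2 ratio of the 13 mRNAs lay 0.62 above the mean of the rRNAs. That argues against fewer mitochondria as the sole source of the rRNA difference and leaves a smaller part undecided. Reads shared with nuclear copies in the annotation are argued against by a posterior SD of the rRNA counts of 0% in both libraries. After the trend with length or GC content was removed, the mean log2 ratio of the rRNAs was -0.73. A difference in how unevenly polyadenylated rRNA was captured or amplified stays open and was not tested, nor was a biological explanation.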

How the results depend on the processing

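The spike-in coefficient of variation and, for the lists, the removed trend, the members detected in both libraries, the red blood cell list without globins and the other backgrounds of the function lists were added after seeing the data. The counts of detected genes (8650 to 15226), of function lists above the random range (9 against detected genes, 16 against all annotated genes and 13 otherwise), of lists below the granule list (17 to 18) and of lists apart between the areas (8 to 11) stayed within 1.5 times the main value under every alternative run. The Pearson correlation was 0.955 with a pseudocount of 0.1 and 0.990 with 5. Genes over 4-fold apart numbered 719 and 8 with those pseudocounts, 153 with no filter, 23 at a summed count of at least 50, 8 at a TPM of at least 1 in both and 14 among protein-coding genes, against 36, so this count depends on low genes. The coefficient of variation was 0.286 with no filter, 0.205 at a summed count of at least 50, 0.161 at a TPM of at least 1 in both, 0.338 with spike-in totals, 0.229 for protein-coding genes and 0.207 for spike-ins only. With counts divided by 10, 117 genes lay beyond counting error. Cell type lists above the random range numbered 8 against all annotated genes and 2 against detected genes, in place of 4. The spike-in share of replicate 2 over replicate 1 was 1.21 without mitochondrial genes, against 1.22. Isoform dominance held for 1263 genes (70.2%, with the same leading transcript in 93.3%) at a TPM of at least 50, for 65.0% with posterior mean shares, and for 1509 (30.5%) at a share of at least 80%. Spike-in scaling moved the median log2 ratio of all expressed genes to -0.28, and list ratios under it are given relative to that. The red blood cell level list fell to percentile 95.7 without replicate 1. Of the 9 lists apart between the areas, 8 stayed outside under every alternative that gave them a value; without its globin genes the red blood cell list had too few members left for a ratio. Leaving out a replicate gave no value for the agreement or for any difference between the areas. Depth limits genes under a few counts, where 1 library can show 0 by chance.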

Other observations

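The values in this part were looked up after the data had been seen. Penk, which encodes the enkephalin precursor, was at 137 TPM in replicate 1 and 71.1 in replicate 2, on 2916 and 1385 counts, and belongs to no list. Spp1, the osteopontin gene, had 2 counts in replicate 1 and 137 in replicate 2. Prox1, a transcription factor placed on the forebrain list as a gene of hippocampal granule cells, was at 14.0 and 12.8 TPM.

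Gm37376, an unclassified transcript on the plus strand of chromosome 19 from 5801941 to 5802393, lies inside Malat1, which runs from 5795690 to 5802672 on the minus strand. It was listed at 74009 and 72659 TPM beside 88719 and 83553 for Malat1. Whether its reads come from either strand was not analysed here. Cdr1, on the minus strand of chromosome X from 61184005 to 61185558, was listed at 1926 and 1907 TPM, and the same limit holds for it, as its locus is known for an abundant circular RNA from the other strand.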
